A study of Mus musculus with 16 samples.

How the data were processed

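Livers of 16 male mice, 4 per combination of diet and feeding state, were profiled by RNA sequencing. Per the labels' protocols, stranded mRNA libraries were prepared after poly-A enrichment, and the data of several lanes were merged for each sample before expression estimation. The deposited table holds RSEM expected counts per gene, per the file headers and name, and 10.2% of its values are not whole numbers. The aligner, the RSEM settings, the genome build and the annotation are not given in the sources used here. The submitters' processing notes name edgeR, limma and R 3.5.3 without their roles. The authors deposited a table for each diet comparison with log2 fold changes, log2 CPM, an F score and p-values with Benjamini-Hochberg adjustment, per the file headers. How the authors filtered genes and built the design is not stated there.

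Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Of 51912 gene identifiers 51633 were matched to a symbol, and 279 had none. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14920 genes. Counts were scaled by TMM, and a robust quasi-likelihood model with 1 mean per group and a spread shared by all 16 libraries was fitted. Each contrast was tested with the quasi-likelihood F test and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. The contrasts were the diet effect (low isoleucine minus control) in fasted and in refed mice, their difference (refed minus fasted), and the feeding effect (refed minus fasted) on each diet. Group levels are means and SDs of TMM-normalised CPM. Gene positions were looked up by identifier in GENCODE M21, which held 14891 of the tested genes; the build behind the deposited counts is not stated, so these positions belong to that annotation alone.

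The design, the alternatives, the 40 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, on log2 CPM with a prior count of 2, and adjusted over the 39 lists with at least 3 tested members. Of the tested genes 25 were on more than 1 list. For each list the members past 0.05 over all genes, and those past 0.05 adjusted over the list alone, were counted. The rule named 10 genes chosen in advance in each diet and feeding comparison. It also named the 8 higher and 8 lower genes with the largest log2 fold change per diet comparison, among genes that passed, had a mean of at least 1 CPM and had every library of one diet above every library of the other. It added up to 4 passing members of each list that passed or had at least 3 passing members, and 6 higher and 6 lower genes per feeding comparison. For the interaction it took 5 higher and 5 lower genes that passed, of which there were none by edgeR. Genes with provisional names were left out, and the report does not give every gene the rule took up. A further 9 lists were written after the called genes were seen and are reported apart, and so was a comparison of ribosomal protein genes with other genes of like exon length and expression. Exon length was the merged length of all exons of a gene in GENCODE M21.

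The method was tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes changed by known folds. The changed genes all had a mean of at least 1 CPM, and no outlying library was simulated. Recovery of scarcer genes, or with such a library, was therefore not measured. For the diet comparison in fasted mice, run on 14708 genes, edgeR recovered 25.7% of genes changed 1.5-fold, 64.3% of those changed 2-fold and 96.7% of those changed 4-fold, with 6 false calls among 127. For the refed comparison, run on 14705 genes, it recovered 20%, 67.1% and 96.7%, and for the interaction, run on 14705 genes, 0%, 31.4% and 85%. DESeq2 made 30 false calls among 173 in the fasted simulation, run on 14338 genes. Camera found the simulated changed set among 30 sets and called 0 others, on 14680 genes, with the preset and with the estimated correlation. The simulated genes were drawn independently, so this did not test camera on lists whose members vary together.

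The alternatives were DESeq2 size factors, upper-quartile scaling and library size alone in place of TMM, no filter or at least 1 CPM in at least 4 libraries in place of filterByExpr, the DESeq2 Wald test and limma-voom in place of edgeR, only the compared groups in the fit, a non-robust fit, a replicate block by the mark in the labels, an added fold threshold, and leaving out each library in turn. The DESeq2 Wald test was run on all genes with a count and not on those kept by filterByExpr. A fit without mitochondrial, Mup and Alb transcripts was added after the data were seen. The alternative for normalised values was not needed, because the table held expected counts. Total counts of 24368656 to 34002955 per library set the depth, and counting error is not separated from biological spread in the SDs given. All 16 libraries were used and none was left out of the comparisons.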

Results

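Poly-A enriched RNA of 16 livers was sequenced, 1 library per male mouse. The mice had eaten a control amino acid diet or a diet low in isoleucine, a branched-chain essential amino acid, for 3 weeks from 10 weeks of age, and were 13 weeks old at harvest. Livers were taken after a 16 h fast or after refeeding, which gave 4 groups of 4 libraries. Total counts ran from 28538541 to 32751692 in the control fasted group, 29460888 to 34002955 in the low isoleucine fasted group, 24368656 to 33432158 in the control refed group and 30405595 to 33822517 in the low isoleucine refed group. Of 51912 genes in the count table, 14920 had enough counts to be tested. Levels below are TMM-normalised CPM, which are counts scaled to a common library size, given as mean ± SD with n = 4 libraries per group. Each group carried a single number in its labels (1, 2, 7 and 9), so whatever that number stands for cannot be separated from diet and feeding state.

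Feeding state separated the libraries most. The first principal component carried 28.6% of the variance, and its scores ran from -36.4 to -25.4 in the 8 fasted libraries and from 13.7 to 42.8 in the 8 refed libraries. Transcripts of the major urinary protein (Mup) family took 9.93% ± 1.77 of the counts in control fasted livers and 4.74% ± 1.67 in low isoleucine fasted livers (SD, n = 4). The shares were 8.49% ± 4.57 in control refed and 5% ± 1.5 in low isoleucine refed livers. Control refed library 4 stood apart from the other refed libraries, with the lowest refed score on the first component (13.7), a Mup share of 2.81% and a TMM factor of 1.21. In that library the marker lists of Kupffer cells, stellate cells, endothelial cells, lymphocytes and neutrophils were each at their highest level among the 16 libraries, by 0.77, 1.15, 1.03, 1.27 and 1.44 log2 units above the mean of the other 3 control refed libraries.

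**Figure D1:**
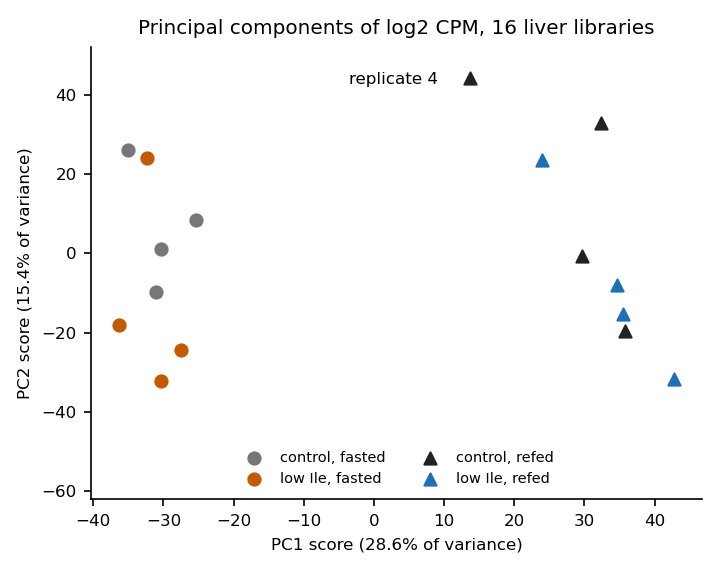
Principal component scores of the 16 libraries from log2 CPM of the tested genes, with a point per library coloured by group; the axes carry 28.6% and 15.4% of the variance. The fasted libraries lie below -25 on the first component and the refed libraries above 13, with control refed library 4 nearest to the fasted side.

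The first comparison asked how the low isoleucine diet altered the fasted liver. Vldlr, the very low density lipoprotein receptor, rose from 1.82 ± 1.14 to 8.04 ± 0.893 CPM (n = 4 each), a 4.44-fold difference. Cyp39a1, an oxysterol 7-alpha-hydroxylase, rose from 34 ± 4.6 to 114 ± 5.89 CPM. Mup20, a male urinary pheromone protein, fell from 11300 ± 3190 to 1920 ± 823 CPM, and Serpina1e, an alpha-1-antitrypsin gene, fell from 5270 ± 1100 to 641 ± 368 CPM. Of 23 interferon-stimulated genes 7 fell and 16 did not pass, with a median log2 fold change of -0.92, and the list did not pass with an estimated correlation (adjusted p = 0.0962).

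In the edgeR quasi-likelihood test 115 of 14920 genes passed an adjusted p of 0.05 between diets in fasted mice, 49 higher and 66 lower on the low isoleucine diet. The log2 fold changes and adjusted p values were 2.15 (SE 0.341, adjusted p = 0.0143) for Vldlr, 1.75 (SE 0.230, adjusted p = 0.00717) for Cyp39a1, -2.56 (SE 0.387, adjusted p = 0.0143) for Mup20 and -3.04 (SE 0.513, adjusted p = 0.0191) for Serpina1e. In the GENCODE M21 annotation, looked up by gene identifier, Vldlr (ENSMUSG00000024924) lies on chromosome 19 from 27216484 to 27254231, Cyp39a1 (ENSMUSG00000023963) on chromosome 17 from 43667425 to 43751431 and Mup20 (ENSMUSG00000078672) on chromosome 4 from 62050234 to 62054158. Other genes that rose were Slc22a27 (log2 fold change 2.18), Slc34a2, a sodium-phosphate cotransporter (2.13), Rad51b, a DNA repair gene (2.08), Tubb2a, a beta-tubulin (2.07), and Acnat2 (1.77). Other genes that fell were Cib3 (-4.07), Selenbp2 (-3.61), Tff3, a trefoil factor (-2.96), Pls1, an actin-bundling protein (-2.35), H2-Q1, an MHC class I gene (-2.19), and Upp2, a uridine phosphorylase (-1.84). As the naming rule required, each of these genes had all 4 libraries of one diet above all 4 of the other. Mup20, Serpina1e, Selenbp2, Acnat2, Slc22a27 and H2-Q1 belong to families of near-identical copies, so the division of reads among the copies is uncertain.

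All 23 tested interferon-stimulated genes had negative log2 fold changes in fasted mice. Of these, by edgeR 7 fell and 16 did not pass over all genes, 21 were lower when adjusted over the list alone, and DESeq2 called 15 and limma-voom 8 (camera adjusted p = 4.48e-25, and adjusted p = 0.0962 with an estimated correlation). Mx1 fell from 4.55 ± 0.242 to 1.74 ± 0.706 CPM, Oasl1 from 14.9 ± 3.20 to 7.12 ± 0.888, Ifi44 from 6.52 ± 1.35 to 2.67 ± 1.05 and Oas1a from 4.90 ± 1.26 to 2.13 ± 0.228 (n = 4 each). The Kupffer cell and macrophage markers had a median of -0.54, with 12 of 13 negative. Their mean log2 level was 4.35 ± 0.202 in control fasted and 3.85 ± 0.264 in low isoleucine fasted livers. By edgeR 0 of these 13 markers passed over all genes, 0 passed adjusted over the list alone, 7 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each (camera adjusted p = 5.14e-06, and adjusted p = 0.409 with an estimated correlation).

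All 14 tested male-biased liver genes had negative log2 fold changes, with a median of -1.22. By edgeR Mup20 fell, 13 did not pass, and 7 were lower adjusted over the list alone, while DESeq2 called 7 and limma-voom 1 (camera adjusted p = 6.15e-11, and adjusted p = 0.351 with an estimated correlation). Female-biased liver genes had a median of 1.93. Of 10 tested members 2 rose, among them Sult3a1, a sulfotransferase (log2 fold change 3.36), 8 did not pass, and 7 were higher adjusted over the list alone, while DESeq2 called 3 and limma-voom 2 (camera adjusted p = 5.52e-08, and adjusted p = 0.134 with an estimated correlation). Sult3a1 was scarce, at 0.0671 ± 0.0610 CPM in control fasted livers.

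Genes of fatty acid oxidation and ketogenesis had a median of 0.27. Ehhadh, the peroxisomal bifunctional enzyme, rose from 1980 ± 571 to 5260 ± 1550 CPM, and Cyp4a14, a fatty acid omega-hydroxylase, rose from 7740 ± 914 to 13400 ± 1550 CPM. By edgeR the other 26 members did not pass, and 11 were higher adjusted over the list alone, while DESeq2 called 8 members and limma-voom 2 (camera adjusted p = 6.7e-09, and adjusted p = 0.351 with an estimated correlation). Circadian clock genes had a median of -0.54. Ciart (log2 fold change -1.52), Usp2 (-1.33) and Cry2 (-0.57) fell, 16 members did not pass, and adjusted over the list alone 9 were lower and 2 higher, while DESeq2 called 10 and limma-voom 3 (camera adjusted p = 2.57e-05, and adjusted p = 0.0962 with an estimated correlation). The proteasome list had a median of 0.19 with 34 of 38 members positive, although Psmb8, an interferon-inducible immunoproteasome subunit, fell from 16.7 ± 2.54 to 8.41 ± 0.876 CPM. By edgeR no other member of that list passed, and 2 were lower adjusted over the list alone, while DESeq2 called 2 members and limma-voom 1 (camera adjusted p = 3.82e-06 for higher, and adjusted p = 0.351 with an estimated correlation).

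All 79 tested cytosolic ribosomal protein genes had positive log2 fold changes in fasted mice, with a median of 0.32. By edgeR 0 passed over all genes, 0 passed adjusted over the list alone, 34 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each (camera adjusted p = 2.81e-19, and adjusted p = 0.409 with an estimated correlation). The merged length of all annotated exons per gene had a median of 1770 bases for these genes against 4042 for all tested genes. This length covers all transcripts of a gene, so the length of single transcripts was not matched below. In a comparison chosen after the result was seen, other genes were matched within 20% of the merged exon length and 1 log2 unit of the expression. These matches had a median of 0.02, and 79 of 79 ribosomal genes lay above their matches. Branched-chain amino acid catabolism had a median of -0.17 and other amino acid catabolism with the urea cycle -0.22. By edgeR 0 of 25 and 0 of 30 members passed, adjusted over the list alone 3 and 0 were lower, 7 and 7 had an unadjusted p under 0.05, DESeq2 called 2 and 1, and limma-voom 0 and 0 (camera adjusted p = 0.000805 for each, and adjusted p = 0.416 for each with an estimated correlation). Among lymphocyte markers Cd4 fell (log2 fold change -1.76), 12 did not pass, and 1 was lower adjusted over the list alone (camera adjusted p = 0.00156, and adjusted p = 0.456 with an estimated correlation). Among erythroid markers Hbb-bs, a beta-globin with a near-identical neighbour, rose (1.00), 4 did not pass, and adjusted over the list alone 4 were higher and 1 lower, while DESeq2 called 4 and limma-voom 2 (camera adjusted p = 0.00854, and adjusted p = 0.416 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases (median 0.09, camera adjusted p = 0.0434, and adjusted p = 0.741 with an estimated correlation) and gluconeogenesis genes (median -0.15, camera adjusted p = 0.0376, and adjusted p = 0.649 with an estimated correlation) completed the 14 lists that passed. By edgeR 0 of 20 and 0 of 16 of their members passed, 1 and 0 were higher adjusted over the list alone, 2 and 3 had an unadjusted p under 0.05, DESeq2 called 1 and 0, and limma-voom 0 and 0.

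The 10 single genes chosen in advance did not pass between diets in fasted mice. Of 28 genes on the ATF4 amino acid response list Vldlr rose and 27 did not pass, with a median of 0.07 (camera adjusted p = 0.126). Fgf21, a liver hormone of the amino acid response, was at 5.42 ± 1.72 and 13.6 ± 6.65 CPM (log2 fold change 1.33, adjusted p = 0.6), and Asns, asparagine synthetase, at 3.40 ± 1.85 and 8.41 ± 2.34 CPM (1.30, adjusted p = 0.502). Scd1, stearoyl-CoA desaturase, was at 3750 ± 1990 and 1830 ± 330 CPM (-1.04, adjusted p = 0.538). The values for Srebf1, Fasn, Pck1, G6pc, Igfbp1, Cyp7a1 and Bckdk ran from -0.58 to 0.34. The count of 115 varied with the libraries in the fit. It was 52, 25, 40 and 6 without control fasted libraries 1, 2, 3 and 4. It was 203, 7, 14 and 24 without low isoleucine fasted libraries 1, 2, 3 and 4. Without control refed library 4 it was 222, and without low isoleucine refed library 1 it was 71. Leaving out a library also shrinks its group and renews the filter and the shared spread. These counts therefore do not separate lower power from the weight of single libraries. Of the 29 genes named by rule that passed, 1 (Cyp39a1) passed under every alternative tried, and DESeq2 called 371 genes.

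**Figure D2:**
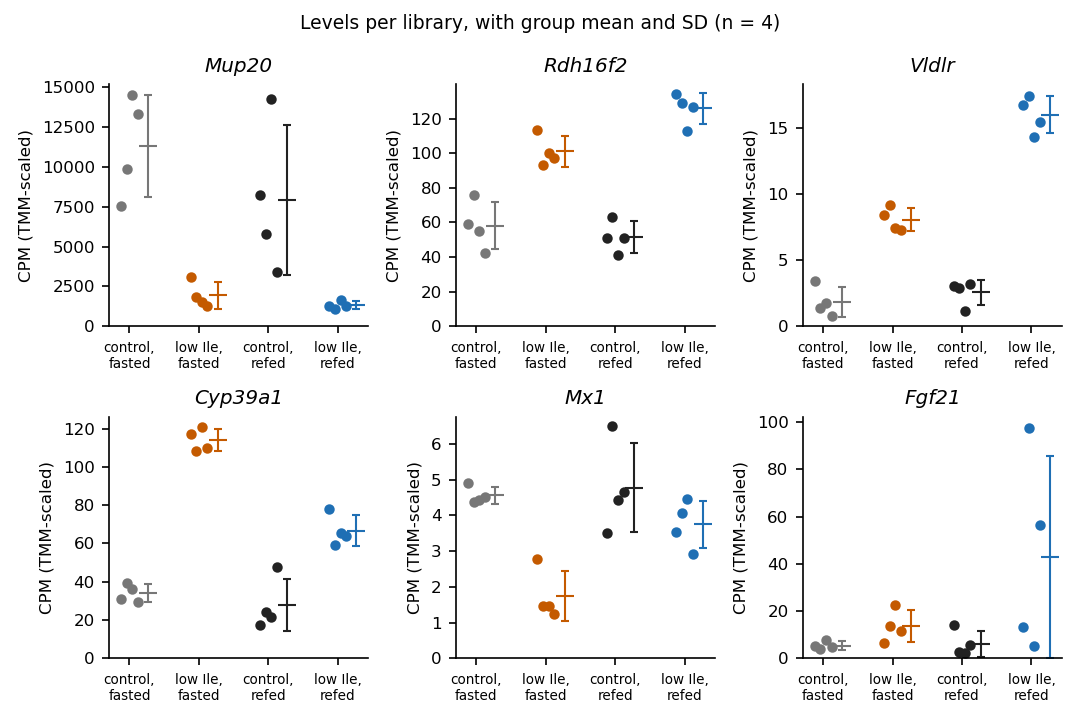
TMM-scaled CPM, on linear axes from 0, of Mup20, Rdh16f2, Vldlr, Cyp39a1, Mx1 and Fgf21 in each of the 16 libraries, with a point per library and the group mean with its SD (n = 4) beside the points. Vldlr and Cyp39a1 were higher and Mup20 lower in all 4 low isoleucine libraries than in all 4 control libraries of the same feeding state. The rule that named these genes required this separation.

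The next comparison asked how the diet altered the refed liver. Vldlr rose from 2.57 ± 0.949 to 16.0 ± 1.39 CPM, and Rdh16f2, a retinol dehydrogenase family member, rose from 51.5 ± 9.17 to 126 ± 9.16 (n = 4 each). Mup20 fell from 7920 ± 4700 to 1320 ± 228 CPM, and C6, a component of the complement membrane attack complex, fell from 242 ± 137 to 63.2 ± 7.41 CPM. Of 28 genes of the ATF4 amino acid response 1 rose and 27 did not pass, with a median log2 fold change of 0.70, and the list did not pass with an estimated correlation (adjusted p = 0.261). Proliferation genes had a median of -0.75, with 0 of 17 passing by edgeR, 9 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom.

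In the edgeR quasi-likelihood test 26 genes passed between diets in refed mice, 9 higher and 17 lower. The log2 fold changes were 2.62 for Vldlr (SE 0.335, adjusted p = 0.00487), 1.29 for Rdh16f2 (SE 0.155, adjusted p = 0.00346), -2.58 for Mup20 (SE 0.387, adjusted p = 0.0148) and -1.94 for C6 (SE 0.318, adjusted p = 0.0222). Rdh16f2 (ENSMUSG00000074639) lies on chromosome 10 from 127866474 to 127877317 and C6 (ENSMUSG00000022181) on chromosome 15 from 4727175 to 4814967 in GENCODE M21. Pcp4l1 (1.86), Cyp2c39, a member of a cluster of similar cytochrome P450 genes (1.49), Cyp39a1 (1.26) and Avpr1a, a vasopressin receptor (0.88), also rose. H2-Q1 (-2.30), Blnk, a B cell adaptor protein (-1.92), Osbpl3 (-1.87), Tent5c (-1.65), Gpc1, a glypican (-1.37), and Atad2 (-1.27) also fell. As the naming rule required, each of these genes had all 4 libraries of one diet above all 4 of the other. Mup20, H2-Q1, Cyp2c39 and Rdh16f2 have near-identical relatives, so their share of reads is uncertain.

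Of 28 tested ATF4 response genes 27 had positive log2 fold changes in refed mice. By edgeR Vldlr rose, 27 did not pass over all genes, and 16 were higher adjusted over the list alone, while DESeq2 called 11 and limma-voom 1 (camera adjusted p = 8.05e-15, and adjusted p = 0.261 with an estimated correlation). Fgf21 was at 6.12 ± 5.48 CPM on the control diet and 43.0 ± 42.7 on the low isoleucine diet (log2 fold change 2.82, adjusted p = 0.24), where libraries 2 and 4 (97.4 and 56.4) carried the mean and libraries 1 and 3 were at 13.2 and 5.03. Proliferation genes were negative in 15 of 17 cases. By edgeR 0 passed over all genes, 7 were lower adjusted over the list alone, 9 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0 (camera adjusted p = 5.6e-09, and adjusted p = 0.013 with an estimated correlation). This was the 1 list of 15 that held with an estimated correlation in refed mice. Male-biased genes had a median of -0.99, with Mup20 lower, 13 not passing, 4 lower adjusted over the list alone, 3 called by DESeq2 and 1 by limma-voom (camera adjusted p = 4.51e-05, and adjusted p = 0.709 with an estimated correlation); without control refed library 3 that median was -0.38. Female-biased genes had a median of 0.50, with 1 higher, 9 not passing, 4 higher adjusted over the list alone, 3 called by DESeq2 and 2 by limma-voom (camera adjusted p = 5.81e-07, and adjusted p = 0.261 with an estimated correlation); it was 0.24 without control refed library 1 and 1.44 without control refed library 2.

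Ribosomal protein genes were again positive in 79 of 79 cases, with a median of 0.33. Their matches of like merged exon length and expression had a median of 0.04, and 75 of 79 ribosomal genes lay above their matches. Across 14891 genes the Spearman correlation of log2 fold change with merged exon length was -0.168 in refed and -0.0163 in fasted mice. By edgeR 0 passed over all genes, 0 passed adjusted over the list alone, 32 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each (camera adjusted p = 4.56e-21, and adjusted p = 0.494 with an estimated correlation). Interferon-stimulated genes had a median of -0.39, or -0.19 without control refed library 2, and Kupffer cell markers -0.45, or -0.24 without control refed library 4, where they were highest, and -0.73 without low isoleucine refed library 3. By edgeR 0 of 23 and 0 of 13 passed, 0 and 0 adjusted over the list alone, 7 and 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 in each (camera adjusted p = 0.000202 and 3.04e-05, and adjusted p = 0.709 and 0.627 with an estimated correlation). Heat shock genes were negative in 11 of 11 cases, with a median of -0.42. By edgeR 0 passed, 0 adjusted over the list alone, 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each (camera adjusted p = 0.00285, and adjusted p = 0.73 with an estimated correlation). The other 7 lists that passed camera, with median and adjusted p with an estimated correlation, were aminoacyl-tRNA synthetases (0.11, adjusted p = 0.73), cholesterol synthesis (0.20, adjusted p = 0.885), bile acid synthesis (0.11, adjusted p = 0.494), xenobiotic metabolism (0.15, adjusted p = 0.78), oxidative phosphorylation (0.12, adjusted p = 0.78), proteasome (0.09, adjusted p = 0.627) and pericentral hepatocyte genes (0.26, adjusted p = 0.709). Their camera adjusted p values with the preset correlation were 0.00598, 0.0168, 0.0166, 0.0277, 0.00124, 0.000613 and 0.00598 in that order.

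Scd1 was at 2640 ± 1950 and 549 ± 289 CPM in refed mice (log2 fold change -2.26, adjusted p = 0.154), and Igfbp1 at 5.11 ± 4.07 and 50.7 ± 50.0 CPM (3.28, adjusted p = 0.259), with 79.0 and 107 in low isoleucine refed libraries 2 and 4 against 9.48 and 7.48 in libraries 1 and 3. Asns, Srebf1, Fasn, Pck1, G6pc, Cyp7a1 and Bckdk ran from -0.26 to 0.46 and did not pass. Control refed library 4 lay outside the other control refed libraries for Fasn (62.2 CPM against 348 to 545) and Srebf1 (31.7 against 66.2 to 112). It also did for Asns (23.2 against 1.25 to 8.30) and Bckdk (7.72 against 8.58 to 13.3), and not for Pck1, G6pc, Cyp7a1 and Fgf21. For Scd1 this library was at 573 CPM against 2165 to 5272 in the others, within the low isoleucine refed range of 334 to 952. For Igfbp1 it was at 10.7 CPM against 0.998 to 4.71, above low isoleucine refed libraries 1 and 3. DESeq2 called Scd1 (adjusted p = 0.00664), Igfbp1 (adjusted p = 0.0261) and Fgf21 (adjusted p = 0.0336), which edgeR did not. In the simulated refed comparison DESeq2 made 26 false calls among 174, against 5 among 124 by edgeR. The count of 26 was 3, 6 and 9 without low isoleucine refed libraries 1, 2 and 4, and 17 and 89 without control refed libraries 3 and 4. It was 179 with DESeq2 and 3 with only the groups compared in the fit, and the cholesterol synthesis list lost its call and turned direction without control refed library 4 (adjusted p = 0.408).

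**Figure D3:**
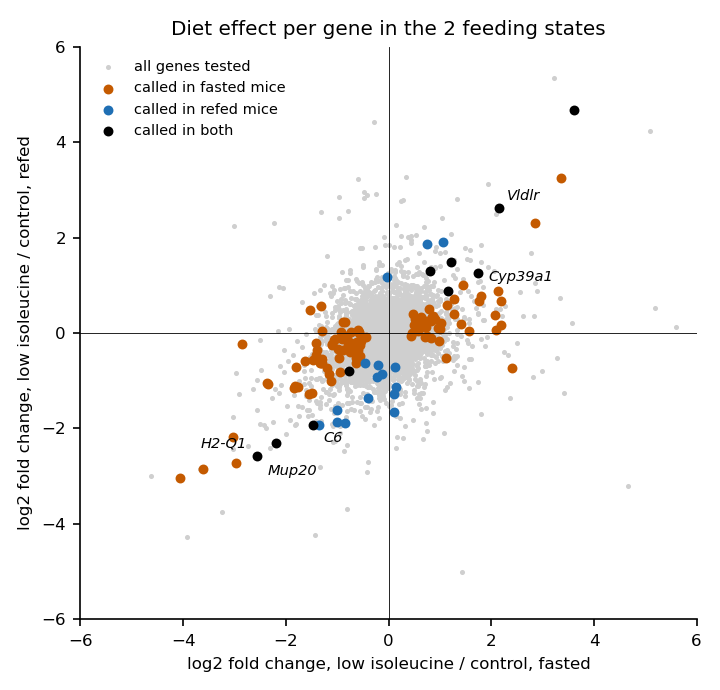
Diet log2 fold change (low isoleucine minus control) of each tested gene in refed mice against that in fasted mice, with 14916 genes inside the axes and 4 genes outside them. The 10 genes that passed in both states, among them Vldlr, Cyp39a1 and Mup20, have the same sign in both.

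Diet effects in the 2 feeding states were set side by side. Their group means share no library, but both tests used the spread shared by all 16 libraries. In both states 10 genes passed, 6 higher and 4 lower in each, among them Avpr1a, C6, Cyp2c39, Cyp39a1, H2-Q1, Mup20, Oas2, Rdh16f2 and Vldlr; Oas2, an interferon-stimulated gene, falls outside the rule for named genes and is given because the count was small. Independent lists would share 0.0296 higher and 0.0752 lower genes, but with the shared spread these 2 lists were not independent. Across 14920 genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.358 and the Spearman correlation 0.263, with a covariance of 0.064. The number shared was 34 without control refed library 4, 1 without low isoleucine fasted library 2, 3 without control fasted libraries 3 or 4, low isoleucine fasted library 4 or low isoleucine refed library 1, 4 without low isoleucine fasted library 3 or low isoleucine refed libraries 2 or 4, 5 without control fasted library 1, and 6 without control refed libraries 1 or 3. With DESeq2, which was run without the low-count filter, it was 49, with a correlation of 0.0779 over all genes with a count. With only the groups compared in the fit it was 2. The edgeR correlation was 0.0516 without a low-count filter and 0.528 among genes of at least 10 CPM.

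**Figure D4:**
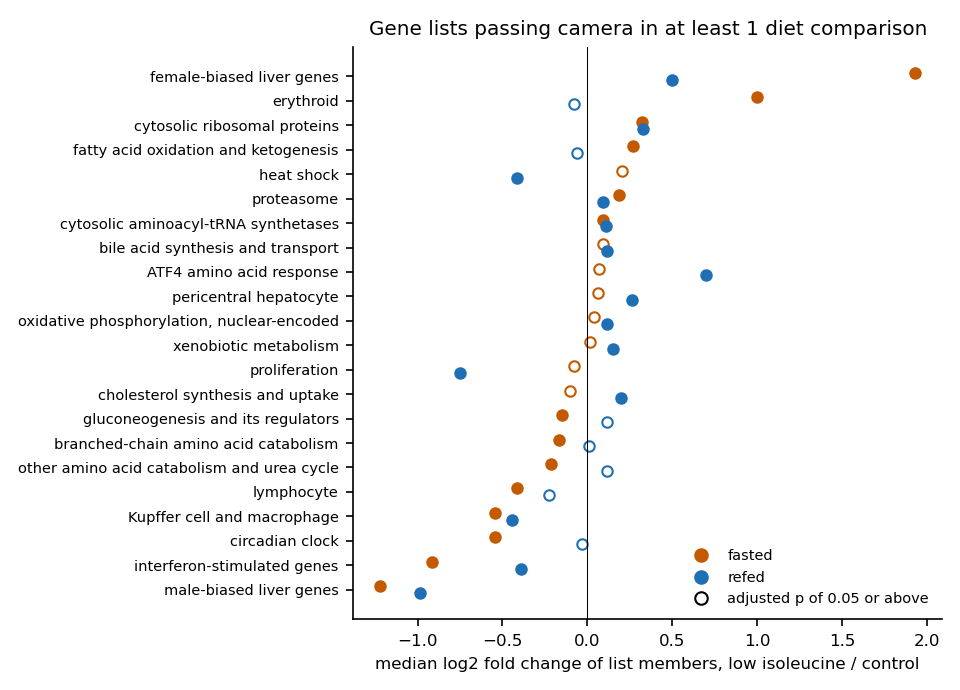
Median log2 fold change of each of 22 gene lists between diets, in fasted and in refed mice, with filled points where camera with the preset correlation passed and open points where it did not. The 7 lists that passed in both states, such as male-biased genes (-1.22 and -0.99) and ribosomal protein genes (0.32 and 0.33), had the same direction in both. None of these 7 passed with an estimated correlation in either state.

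The difference between the diet effects (refed minus fasted) was tested directly. By edgeR 0 genes passed, 928 had an unadjusted p under 0.05 where 746 would by chance, DESeq2 called 35 and limma-voom 0. By DESeq2 Rad51b (log2 difference -2.04, adjusted p = 0.00904), Tent5c (-1.77, adjusted p = 0.0156) and Atad2 (-1.40, adjusted p = 0.0271) passed, so whether named genes respond to diet differently in the 2 feeding states rested on the tool. DESeq2 made 30 false calls among 173 in the simulated fasted diet comparison, against 6 among 127 by edgeR. Its false calls were not simulated for the interaction. The smallest adjusted p by edgeR was 0.285, for Ciart (0.000406 by DESeq2), whose diet log2 fold changes were -1.52 in fasted and 0.49 in refed mice; it is named after its value was seen. Of 39 lists 18 passed camera with the preset correlation, 0 with an estimated correlation, and fry called 0; with the preset correlation 11 passed without control refed library 3. Interferon-stimulated genes had a median difference of 0.67 with 22 of 23 positive (camera adjusted p = 2.65e-10, and adjusted p = 0.443 with an estimated correlation). ATF4 response genes had a median of 0.58 with 26 of 28 positive (camera adjusted p = 2.63e-06, and adjusted p = 0.489 with an estimated correlation). Fatty acid oxidation genes were negative in 28 of 28 cases, with a median of -0.36 (camera adjusted p = 2.12e-06, and adjusted p = 0.443 with an estimated correlation). Adjusted over the list alone, 3 interferon-stimulated, 0 ATF4 and 0 fatty acid oxidation genes passed, and 9, 7 and 5 had an unadjusted p under 0.05; over all genes edgeR called 0, 0 and 0, DESeq2 0, 1 and 0, and limma-voom 0, 0 and 0.

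On the control diet, refeeding was compared with fasting. Fasn, fatty acid synthase, rose from 57.5 ± 19.0 to 344 ± 204 CPM, and Srebf1, a regulator of lipid synthesis, rose from 21 ± 9.09 to 73.0 ± 33.6 (n = 4 each). Pck1, a gluconeogenic enzyme, fell from 3980 ± 326 to 1000.0 ± 455 CPM, Angptl4, an inhibitor of lipoprotein lipase, from 179 ± 26.8 to 22.5 ± 8.63, and Igfbp1 from 97.5 ± 96.3 to 5.11 ± 4.07. In the edgeR test 2552 genes passed, 1329 higher and 1223 lower in refed mice. The log2 fold changes were 2.58 for Fasn (SE 0.470, adjusted p = 0.00185), -1.99 for Pck1 (SE 0.358, adjusted p = 0.00146) and -3.0 for Angptl4 (SE 0.280, adjusted p = 5.91e-06). Angptl4 (ENSMUSG00000002289) lies on chromosome 17 from 33773750 to 33781830 in GENCODE M21. Atp2b2 (3.47), Cyp26a1, a retinoic acid hydroxylase (3.29), Angptl8 (3.19), Mid1ip1 (3.09) and Pnpla3 (2.81) also rose, and Ppp1r3g, a glycogen-targeting phosphatase subunit (-6.44), Zbtb16 (-3.46), Mt2, a metallothionein (-3.24), and Zbed5 (-2.96) also fell. Cyp7a1, Asns, Bckdk, Fgf21, Scd1 and G6pc did not pass, though DESeq2 called G6pc (adjusted p = 0.0265).

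Of 28 fatty acid oxidation genes 15 fell and 13 did not pass, and 18 were lower adjusted over the list alone (median -0.48, camera adjusted p = 7.57e-09, and adjusted p = 0.343 with an estimated correlation). Of 16 gluconeogenesis genes, Pck1 and Igfbp1 among them, 9 fell and 7 did not pass, and 11 were lower adjusted over the list alone (median -1.02, camera adjusted p = 3.82e-07, and adjusted p = 0.343 with an estimated correlation). Of 22 ER chaperone genes 15 rose and 7 did not pass, 17 were higher adjusted over the list alone, and limma-voom called 7 (median 0.91, camera adjusted p = 6.16e-07, and adjusted p = 0.491 with an estimated correlation). Of 25 cholesterol synthesis genes 7 rose and 18 did not pass, 15 were higher adjusted over the list alone, and DESeq2 called 14 (median 0.94, camera adjusted p = 2.6e-06, and adjusted p = 0.542 with an estimated correlation). Of 13 glucocorticoid-responsive genes, Zbtb16 and Mt2 among them, 6 fell and 7 did not pass, and 7 were lower adjusted over the list alone (median -0.92, camera adjusted p = 0.00025, and adjusted p = 0.343 with an estimated correlation). In all 18 of 39 lists passed camera with the preset correlation, 0 with an estimated correlation and 15 by fry. With library size as the only scaling the median of all genes was 0.135 against 0.0132 with TMM, and 71.7% of the calls were higher against 52.1% with TMM.

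On the low isoleucine diet, refeeding was compared with fasting in the same way. Chac1, a glutathione-degrading enzyme of the ATF4 response, rose from 0.411 ± 0.186 to 12.8 ± 12.7 CPM, and Atf3, a stress-induced transcription factor, rose from 0.996 ± 0.206 to 15.5 ± 10.8. Refed libraries 2 and 4 carried the mean of Chac1, with 16.3 and 29.2 CPM against 4.67 and 0.988 in libraries 1 and 3. Aacs, acetoacetyl-CoA synthetase, rose from 3.90 ± 1.07 to 46.1 ± 10.2 CPM, and Fasn rose from 57.2 ± 8.42 to 311 ± 92.8 (n = 4 each). Pdk4, an inhibitor of pyruvate dehydrogenase, fell from 42.7 ± 25.8 to 3.91 ± 1.30 CPM, and Mfsd2a, a lysophospholipid transporter, fell from 147 ± 47.5 to 12.5 ± 1.34. In the edgeR test 3194 genes passed, 1433 higher and 1761 lower in refed mice. The log2 fold changes were 4.96 for Chac1 (SE 0.894, adjusted p = 0.00132), 3.96 for Atf3 (SE 0.492, adjusted p = 5.14e-05), -3.45 for Pdk4 (SE 0.438, adjusted p = 7.85e-05) and -3.56 for Mfsd2a (SE 0.388, adjusted p = 1.92e-05). Chac1 (ENSMUSG00000027313) lies on chromosome 2 from 119351229 to 119354381 in GENCODE M21. Hsd3b5 (3.79), Mthfd2, a mitochondrial folate enzyme (3.79), Gadd45a (3.67) and Srebf1 (2.21) also rose, and Ppp1r3g (-5.89), Angptl4 (-3.62), Npnt (-3.21), Zbtb16 (-3.19), Pck1 (-1.86), Scd1 (-1.74) and G6pc (-1.56) also fell. Igfbp1, Cyp7a1, Asns, Bckdk and Fgf21 did not pass.

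Of 28 fatty acid oxidation genes, Pdk4 and Angptl4 among them, 23 fell and 5 did not pass, and 26 were lower adjusted over the list alone (median -0.80, camera adjusted p = 1.7e-15, and adjusted p = 0.51 with an estimated correlation). Of 28 ATF4 response genes 14 rose, 2 fell and 12 did not pass, and adjusted over the list alone 18 were higher and 2 lower (median 1.18, camera adjusted p = 4.97e-05, and adjusted p = 0.799 with an estimated correlation). For refeeding on the control diet edgeR called 9 of these 28 genes in either direction, DESeq2 11 and limma-voom 4. There Atf3 ran from 0.751 to 1.45 CPM in fasted and 3.46 to 5.24 in refed libraries. Mthfd2 ran from 0.355 to 0.553 and 1.11 to 3.55 CPM, while the ranges of Chac1 overlapped. The response to refeeding was thus not confined to the low isoleucine diet. Of 23 interferon-stimulated genes 15 rose and 8 did not pass, and 17 were higher adjusted over the list alone (median 0.75, camera adjusted p = 3.86e-09, and adjusted p = 0.643 with an estimated correlation). Of 25 cholesterol synthesis genes 17 rose and 8 did not pass, and 21 were higher adjusted over the list alone (median 1.27, camera adjusted p = 3.07e-08, and adjusted p = 0.799 with an estimated correlation). In all 11 of 39 lists passed camera with the preset correlation, 0 with an estimated correlation and 11 by fry. Between the diets 1689 genes passed for feeding in both, 782 higher, 906 lower and 1 with opposite signs. Independent lists would share 128 higher and 144 lower, but these lists came from a fit with a shared spread and were not independent. With library size as the only scaling the median of all genes was 0.130 against 0.0196 with TMM, and 64.5% of the calls were higher against 44.9% with TMM.

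The authors' tables of the diet comparisons were set beside the fit made here. At an adjusted p of 0.05 the authors' table for fasted mice called 91 genes, of which 72 were also called here, all 72 with the same sign. For refed mice it called 39 genes, of which 25 were also called here with the same sign. The 72 shared genes were 38, 24, 29 and 5 without control fasted libraries 1, 2, 3 and 4 and 6, 12 and 17 without low isoleucine fasted libraries 2, 3 and 4. The 25 shared genes were 14 and 15 without control refed libraries 2 and 3 and 3, 6 and 9 without low isoleucine refed libraries 1, 2 and 4. In the authors' tables the log2 fold changes of Mup20 were -2.56 (adjusted p = 0.00157) in fasted and -2.58 (adjusted p = 0.00195) in refed mice, and those of Vldlr 2.14 (adjusted p = 0.0132) and 2.63 (adjusted p = 0.00195). Across the 14102 genes matched in fasted mice the Pearson correlation of the log2 fold changes was 0.984, and across the 14082 matched in refed mice 0.999. Selenbp2, called here in fasted mice, had an adjusted p of 0.0513 in the authors' table.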

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

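The tests of control refed library 4 as a fasted library and for depth were chosen after the result was seen; the other tests were written before their results, except for a condition on the spread described with that library. Among 304 groups of 4 libraries checked for a single library far from the others (67 named genes and 9 library measures), 17 passed Dixon's critical ratio of the gap to the range, where chance flags about 1 in 20 groups, or 15.2 here.

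In control fasted mice the ratio of the gap to the range was 0.945 for Tff3, 0.939 for Cyp4a14 and 0.96 for Tent5c in library 1, and 0.85 for Igfbp1 and 0.868 for Usp2 in library 3. In control refed mice it was 0.901 for Oas1a and 0.855 for Cyp26a1 in library 2, 0.905 for Vldlr and 0.845 for Mfsd2a in library 3, and 0.919 for Npnt and 0.916 for the third principal component in library 4. In low isoleucine refed mice it was 0.87 for Acnat2 and 0.905 for Sult3a1 in library 1, 0.877 for Ehhadh in library 2, and 0.83 for Cyp7a1, 0.885 for Aacs and 0.924 for the TMM factor in library 3.

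For 18 lists the diet effects in refed and fasted mice differed by camera with the preset correlation, and for 0 of them with an estimated correlation. The median differences in log2 fold change (refed minus fasted) were -0.915 for erythroid, -0.707 for heat shock, -0.401 for proliferation, -0.373 for ER chaperone, -0.362 for fatty acid oxidation and -0.173 for ribosome biogenesis genes. They were 0.0827 for oxidative phosphorylation, 0.136 for branched-chain amino acid catabolism, 0.163 for acute phase, 0.183 for cholesterol synthesis, 0.22 for glucocorticoid-responsive and 0.23 for other amino acid catabolism genes. They were 0.29 for gluconeogenesis, 0.475 for circadian clock, 0.583 for ATF4 response, 0.667 for interferon-stimulated and 0.678 for immediate early genes. For male-biased genes the median was -0.0209, while the mean was 0.233 and camera called the list higher, so the signs differ.

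Other splits of the same libraries were fitted in the same way. The rule set beforehand asked that a share under 0.05 of the splits, the real one included, give as many genes. It was met for the 115 genes between diets in fasted mice (1 of 35 splits gave as many, highest other 0). It was also met for the 2552 genes between feeding states on the control diet (1 of 35, highest other 12) and the 3194 on the low isoleucine diet (1 of 35, highest other 4). A share of 0.0286 is the smallest that 35 splits can give, so chance was made less likely and not excluded. The rule was not met for the 26 genes between diets in refed mice, where 2 of 35 splits gave as many. The highest other, with 41 genes, set control refed library 1 with low isoleucine refed libraries 1, 2 and 4 against the rest. Nor was it met for the 928 genes with an unadjusted interaction p under 0.05, where 27 of 100 labellings gave as many. The highest of these gave 4832, several times the real count. It set low isoleucine fasted libraries 2, 3 and 4 with control refed libraries 2, 3 and 4, so the diet effects could enter that difference. Whether the samples hold a further structure was not tested.

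Male-biased genes had negative medians between diets in both feeding states, with 1 of 14 members passing in each, and the list did not pass with an estimated correlation (adjusted p = 0.351 and 0.709). Reads shared between Mup copies were tested on the 7 members outside the Mup family, whose medians were -1.21 in fasted and -1.03 in refed mice, the higher being -1.03 where this cause needed a value above -0.3 in one state. A single library was tested by leaving out each in turn, and the highest median was -0.383. The diet stays a candidate explanation, as a hypothesis, and whatever the single label number of each group stands for stays open beside it.

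Interferon-stimulated genes had a negative median between diets in fasted mice, with 7 of 23 members passing and 16 not, and the list did not pass with an estimated correlation (adjusted p = 0.0962). Fewer macrophages were tested with the mean Kupffer list level as a covariate, and the median was -0.926 with it against -0.916 without, while 4 members were called with it and 83 genes in all. The covariate was fitted on differences within groups. Control refed library 4 lay 0.766 log2 units above the mean of the other control refed libraries (SD 0.225). The outcome rests partly on that library, so the test cannot exclude fewer macrophages. A single library was tested by leaving out each fasted library, and the highest median was -0.841. The diet and the label number of each group may each account for the pattern, and neither was separated by these tests. A part played by fewer macrophages stays open beside them.

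Control refed library 4 lay apart from the other refed libraries. A fasted library under a refed label would need a score among the fasted ones on the first component of the other 15 libraries; its score of 9.31 lay 34 above the highest of them, against an SD of 3.94, and its total count was 3.64 M above the highest of the other control refed libraries. RNA of other cell types was to raise a marker list more than 1 log2 unit above all 15 other libraries; the largest excess was 0.668. That argues against it only narrowly: a condition on the spread (SD 0.33) was added after the value was seen and just met, a further version applied list by list left the outcome open, and 5 of 8 such lists were highest in this library. A contribution of other cells therefore may still be present, and no biological explanation was tested.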

How the results depend on the processing

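The fit without mitochondrial, Mup and Alb transcripts was chosen after seeing the data (113 and 25 genes between diets in fasted and refed mice); the other alternatives were written before. No named gene that passed turned direction. Of the named genes that passed, 1 of 29 in fasted and 2 of 15 in refed diet comparisons kept their call under every alternative, and 15 of 15 and 15 of 17 in the feeding comparisons on the control and low isoleucine diets. The causes of the changes below were not tested, except that a fold threshold removes genes and an estimated correlation widens the list test.

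The fasted diet count of 115 ran from 6 to 222 over single left-out libraries, was 371 with DESeq2, 193 with only the groups compared and 59 with an absolute log2 fold change of at least 1. The refed diet count of 26 ran from 3 to 89, and was 179 with DESeq2 and 3 with only the groups compared. The interaction count of 0 by edgeR (928 at an unadjusted p under 0.05) ran from 0 to 1, the 1 being without low isoleucine fasted library 1, and was 35 with DESeq2 and 0 with limma-voom. The feeding counts of 2552 and 3194 ran from 1817 to 2743 and from 2423 to 3601, and were 670 and 870 with the fold threshold. With library size alone 71.7% and 64.5% of feeding calls were higher, against 52.1% and 44.9%, and the median of all genes was 0.135 and 0.130, against 0.0132 and 0.0196.

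With an estimated correlation the passing lists numbered 0 for the diet in fasted mice, 1 in refed mice, 0 for the interaction and 0 and 0 for feeding; fry called 3 and 2 for the diet comparisons, 0 for the interaction and 15 and 11 for feeding. The DESeq2 statistics, from a fit without the low-count filter, gave 23 lists in refed mice. Over left-out libraries the passing lists ran from 13 to 16, 12 to 18, 11 to 19, 13 to 19 and 9 to 13 in the same order, the 11 being without control refed library 3. Lists that turned direction were cholesterol synthesis in the refed diet comparison and in the interaction without control refed library 4 (adjusted p = 0.408 and 0.717, ranges over left-out libraries from 0.000164 and 0.00043) and oxidative phosphorylation in the interaction without low isoleucine refed library 4 (adjusted p = 0.976, range from 0.00132).

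The 10 genes shared between the diet effects ran from 1 to 34 over left-out libraries, and were 6 without a filter, 49 with DESeq2, 2 with only the groups compared and 6 among genes of at least 10 CPM. The correlation of 0.358 ran from 0.275 to 0.341 over left-out libraries, always below the full value. Each of these fits also reran the low-count filter with a smaller group, so the range does not show the weight of single libraries alone. It was 0.0516 without a filter, 0.0779 with DESeq2, also unfiltered, and 0.528 among genes of at least 10 CPM. The 72 and 25 genes shared with the authors' tables ran from 5 to 87 and from 3 to 30, were 3 and 2 at a threshold of 0.01, and for refed mice were 39 with DESeq2 and 3 with only the groups compared.

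The replicate block by label mark gave 77, 25, 0, 2301 and 2983 genes in the order above, the 0 by edgeR. The marks gave no consistent pairing of the samples. Same-mark correlations of deviations ran from -0.195 to 0.213 between the fasted groups, -0.204 to 0.291 between the refed groups, -0.172 to 0.188 between the control groups and -0.259 to 0.229 between the low isoleucine groups, and 0, 1, 2 and 1 of 4 marks correlated best with their own. At this depth and spread the simulated recovery of 1.5-fold changes was 25.7% in the fasted and 20% in the refed comparison, so changes of that size were often not detectable.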

Other observations

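The lists in this part were all written after the called genes were seen. Tubulin genes had a median log2 fold change of 0.78 between diets in fasted mice; Tubb5, Tuba1b, Tuba4a, Tubb4b, Tuba1c and Tubb2a rose and 6 of 12 did not pass (camera adjusted p = 2.9e-08, and adjusted p = 0.0266 with an estimated correlation). Genes of MHC class I and the immunoproteasome had a median of -0.50 with 21 of 21 negative; Psmb8, H2-Q7, H2-Q6, Nlrc5 and H2-Q1 fell (camera adjusted p = 1.2e-16, and adjusted p = 0.0266 with an estimated correlation). Complement genes had a median of -0.31 with 16 of 18 negative; C9, C6, C2 and C8a fell (camera adjusted p = 4.31e-08, and adjusted p = 0.0761 with an estimated correlation). Of the 9 such lists 5 passed camera with the preset correlation in fasted mice, the others being serpin A genes (median -0.27, adjusted p = 0.112 with an estimated correlation) and carboxylesterases (-0.26, adjusted p = 0.477 with an estimated correlation). In refed mice the tubulin median was -0.07 with 7 of 12 negative and 0 passing (camera adjusted p = 0.594), that of MHC class I and the immunoproteasome -0.08 with 16 of 21 negative and H2-Q1 lower (camera adjusted p = 0.0483, and adjusted p = 0.848 with an estimated correlation), and that of complement -0.21 with 15 of 18 negative and C6 lower (camera adjusted p = 1.48e-05, and adjusted p = 0.234 with an estimated correlation). The lists were picked from the same libraries, so the tests are not independent evidence of their direction.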
